A study of Mus musculus with 6 samples.

How the data were processed

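Islet RNA from 3 BPA-treated and 3 vehicle-treated samples of OF1 male mice was measured on 6 Affymetrix arrays, with biotin-labelled cRNA made from 1 µg of total RNA, per the labels' protocols. The labels do not give 1 account of the treatment. The series' design gives 100 µg/kg/day of BPA under the skin, split into injections of 50 µg/kg, for 4 days, with 100 µL of corn oil as vehicle and islets isolated 16 hours after the last injection. The samples' treatment protocol gives 2 days at the same daily dose, and the source names of the BPA samples give 1 nM for 48 hours. Which of these applied stays open. The labels call the samples biological replicates, and the design speaks of 3 experiments per replicate; how many animals entered each sample is not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

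The authors deposited 1 value per probe set and array on the log2 scale, scaled alike over the 6 arrays (medians 6.55 to 6.65). MAS5 was named without a version, per the submitters' processing notes. The narrow low end of the values (lowest 2.95 to 3.04 per array) is unlike plain MAS5 signals, so the method that summarised the probes, and the scaling, stay open. That limits what can be said of dim probe sets, whose spread depends on the method. The values were used as deposited, since the medians differed by less than 0.5. There are no detection calls in the table used here.

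Genes were named from the platform annotation. Of 45101 probe sets, 64 array controls were set aside. Of the other 45037, 34945 had 1 gene, 932 several and 9160 none; symbols of 34741 matched the reference gene table. Probe sets with a mean log2 signal above the median of all (6.60) were kept, which left 22518, 19386 of them with 1 gene. For gene lists and named genes, each of 11787 genes was represented by its kept probe set with the highest mean over the 6 arrays.

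BPA was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided, Benjamini-Hochberg adjustment over the kept probe sets, threshold 0.05). Of 34 gene lists, 33 had the minimum of 5 measured genes and were tested by camera with a preset correlation of 0.01, and beside it with an estimated correlation, on ranks and by fry. The lists held 1055 genes, of which 925 were named on the array and 780 measured. Lists, tests and the rule for naming genes were set before the data were examined. Genes were named by 3 parts of that rule: 12 per direction past the threshold without overlap between groups, filled up by the smallest p without overlap; 16 genes of islet hormones, receptors and channels in every case, of which 1 is not reported here; and list members past the test, or the 2 with the smallest p in lists that camera called. Brightest probe sets are given with no test for genes below the filter. Single values were compared by exact permutation tests, which cannot go below 0.1 with 3 against 3 arrays.

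The test was tested on simulated data: in 20 simulated sets of the 22518 probe sets, 100 were changed by 1 and 100 by 2 on the log2 scale. A list of 30 genes shifted by 0.5 was called in 20 of 20 simulated sets by camera with the preset correlation. Noise in those sets was independent between genes, and the largest median of a real list was 0.29. The result therefore does not show how the list test behaves with correlated genes or with smaller shifts.

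Alternatives were other scalings (quantile, median centring, cyclic loess), no filter or a filter at the 75th percentile, eBayes without a trend or robust, the replicate number as a block, each array left out, the mean of a gene's probe sets, an ordinary test and other thresholds. Figures were drawn with matplotlib in Python.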

Results

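Gene expression was measured in pancreatic islets of OF1 male mice, 10 weeks old, that had received bisphenol A (BPA), a plasticiser that binds oestrogen receptors, or its corn oil vehicle. Each group held 3 samples, each hybridised to its own Affymetrix 3′ expression array, and the series' title asks what short exposure to BPA in the living animal does to islets. The labels disagree on how BPA was given and for how long, so the treatment behind these values stays open. The table held 45101 probe sets, of which 22518 entered the tests. The median log2 signal per array lay between 6.55 and 6.65, and the highest signal per array between 15.24 and 15.32. Pairs of arrays correlated at 0.976 to 0.993 over all probe sets other than the array controls, and the lowest correlation within a group (0.982) lay below the highest between groups (0.993). The latter pair was control replicate 3 with BPA replicate 3. The first principal component of the tested probe sets, their main axis of variation, held 55.9% of the variance. It scored these 2 arrays at 47.2 and 36.3 and the others at -37.5 to -3.2. The number of arrays limits the precision of every value.

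The comparison of BPA with vehicle asked which transcripts differ after treatment. Sncg, which encodes gamma-synuclein, had a log2 signal of 8.33 ± 0.29 after BPA and 7.25 ± 0.14 in controls (SD, n = 3 per group), 2.10 times the control signal. Prrc2c, which encodes an RNA-binding protein, had 9.30 ± 0.15 after BPA against 10.30 ± 0.20 in controls (SD, n = 3 per group), so controls had 2.00 times the signal of BPA. The ATP synthase subunits Atp5g2 and Atp5l differed by 0.56 ± 0.11 and 0.44 ± 0.09 (log2, SE), the cristae protein gene Micos13 by 0.62 ± 0.13 and the dehydrogenase gene Hsd17b10 by 0.64 ± 0.13. None of these differences passed the test: limma gave an adjusted p of 0.655 for each.

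In limma's moderated test, 0 probe sets had higher and 0 had lower signal after BPA at an adjusted p under 0.05, and the smallest adjusted p was 0.655. At an unadjusted p under 0.05 there were 1458 probe sets (864 higher, 594 lower), where 1126 would be expected by chance. Probe sets are not independent, so the count can lie far from that without an effect. The other 9 splits of the 6 arrays into 3 and 3 gave 126 to 3313, and 3 of them gave more than 1458. The ordinary test without moderation gave 0 after adjustment and 1446 before it. The groups did not overlap for 2743 probe sets, which is 12.2% where chance gives 10%. In simulated arrays with the spread of the real ones, the same test recovered 53.4% of probe sets changed by 1 on the log2 scale and 88.5% of those changed by 2. In each simulated set 100 probe sets were changed by each size. The adjustment depends on how many change, so recovery would be lower if only a few did. The counts of 0 held with each of the 6 arrays left out in turn.

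With no gene past the threshold, the 12 genes per direction with the smallest p and no overlap between groups are described as values. Those with higher signal after BPA differed by 0.44 to 1.07 (log2). Beside Sncg, Atp5g2, Atp5l, Micos13 and Hsd17b10 they were Rtl8c at 0.74 ± 0.14 (SE), 2010320M18Rik at 0.64 ± 0.11, Cops6 of the COP9 signalosome at 0.63 ± 0.12, Snf8 of the endosomal sorting machinery at 0.62 ± 0.12, Copz2 of the COPI coat at 0.51 ± 0.11, the glutathione transferase gene Gstm5 at 0.49 ± 0.10 and Ost4 of the oligosaccharyltransferase at 0.45 ± 0.09. A further probe set of Cops6 differed by -0.021. The genes with lower signal included the splicing kinase gene Srpk2 at -0.73 ± 0.13, the chromatin remodelling gene Rsf1 at -0.87 ± 0.19, the histone methyltransferase gene Kmt2c at -0.43 ± 0.10 and the ubiquitin ligase gene Mid1 at -0.87 ± 0.18. Cds1, which encodes an enzyme of phospholipid synthesis, differed by -0.67 ± 0.14, the phosphatase gene Dusp4 by -0.56 ± 0.13 and the co-chaperone gene Dnaja4 by -0.49 ± 0.09. Bend7 (-0.58), Unc45b (-0.54), the transcription factor gene Klf7 (-0.41) and Evi5 (-0.41) completed the 12. Other probe sets of these genes differed less in size: the 5 of Srpk2 lay between -0.47 and 0.065, and the 3 of Rsf1 between -0.38 and 0.12.

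**Figure D1:**
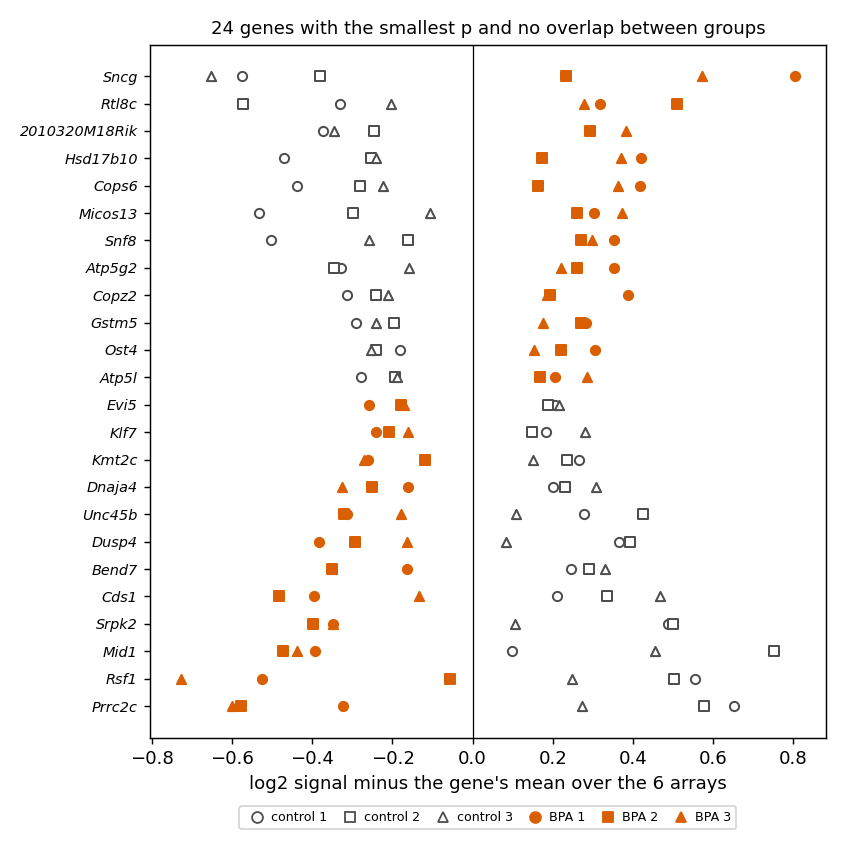
Log2 signal on each array minus the gene's mean over the 6 arrays (x axis) for the 12 genes per direction with the smallest p and no overlap between groups. Open symbols are control arrays, filled symbols BPA arrays, and the shape gives the replicate number; the groups lie apart for every gene shown because the genes were chosen so, and each has an adjusted p of 0.655.

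The hormone genes of the islet were near the top of the signal range and did not differ past the test. Ins2, an insulin gene, was 15.29 ± 0.05 after BPA and 15.29 ± 0.02 in controls (SD, n = 3 per group), close to the highest value on any array, which limits what a difference there can show. Glucagon (Gcg) was 15.02 ± 0.06 against 15.10 ± 0.04, and somatostatin (Sst) 13.94 ± 0.14 against 13.77 ± 0.11. Pancreatic polypeptide (Ppy) was 14.40 ± 0.38 after BPA against 13.98 ± 0.11 in controls, a difference of 0.42 ± 0.18 (SE, adjusted p = 0.787). The BPA replicates read 14.04, 14.37 and 14.79, and the difference ranged from 0.225 to 0.997 over 20 alternatives. Pdx1, a transcription factor of beta cells, was lower in all 3 BPA arrays, at 11.08 ± 0.05 against 11.29 ± 0.05, a difference of -0.21 ± 0.09 (SE) that did not pass the test (adjusted p = 0.781). Its other tested probe set differed by -0.043 ± 0.122, with overlapping groups. The glucose transporter gene Slc2a2 differed by -0.037 ± 0.081 and the genes of the ATP-sensitive potassium channel, Abcc8 and Kcnj11, by -0.011 ± 0.109 and 0.18 ± 0.14. Ins1 had no probe set under its name and was not analysed here.

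Among the receptors that BPA binds, Esr1 and Esr2 lay below the signal filter and were not tested. The brightest probe set of Esr1 read 6.20 ± 0.10 after BPA and 5.89 ± 0.17 in controls, and that of Esr2 5.02 ± 0.15 against 4.91 ± 0.17 (SD, n = 3 per group). Dimmer probe sets of Esr1 differed by -0.059 and 0.077 (log2), also without a test. Gper1, the membrane oestrogen receptor gene, differed by -0.10 ± 0.19 (SE, adjusted p = 0.942). Of the ion channel genes, Cacna1e also lay below the filter, at 6.30 ± 0.41 after BPA and 6.03 ± 0.12 in controls. Kcnma1, the large-conductance potassium channel gene, differed by -0.027 ± 0.129 on its brightest probe set (adjusted p = 0.981), while its 3 other tested probe sets ranged from -0.89 to 0.016. The sodium channel gene Scn9a differed by -0.037 ± 0.127 on its brightest probe set (adjusted p = 0.969). Its probe sets disagreed. Of the other 3 tested, 1 read 8.17 ± 0.35 after BPA and 9.52 ± 0.42 in controls, another 7.09 ± 0.12 against 8.16 ± 0.51 (SD, n = 3 per group), both lower in all 3 BPA arrays, by -1.35 ± 0.26 and -1.07 ± 0.25 (SE) with an adjusted p of 0.655 each. The remaining probe set differed by -0.25 ± 0.16. The smallest p of the whole table belonged to Ceacam1, named here after its values were seen. Of its tested probe sets 3 differed by -1.54, -1.14 and -0.77 (adjusted p = 0.655 each). The other 2 differed by 0.17 and -0.088, the latter on its brightest probe set, so the probe sets of this gene disagreed too.

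**Figure D2:**
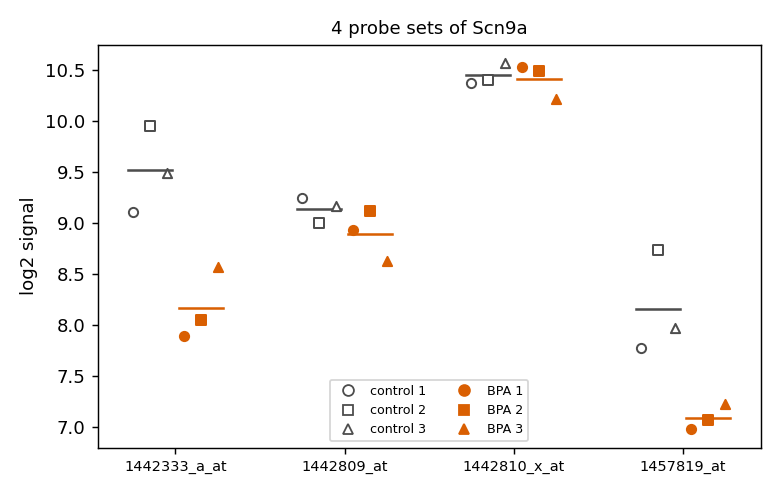
Log2 signal (y axis) of the 4 tested probe sets of Scn9a on each array; open symbols are controls, filled symbols BPA, lines group means (n = 3). The BPA arrays lie below the control arrays for the leftmost and rightmost probe sets, by -1.35 and -1.07, and overlap them for the other 2.

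Of the 33 gene lists fixed beforehand, 8 shifted in limma's camera with a preset correlation of 0.01 at an adjusted p under 0.05, 6 up and 2 down. None of the 8 passed with an estimated correlation, where the smallest adjusted p was 0.418, and 14% of simulated data sets with no effect gave 8 or more lists. All 22 measured genes of glycolysis and of genes normally repressed in beta cells had higher signal after BPA, with a median of 0.29 (log2) and quartiles of 0.14 and 0.38. Triose phosphate isomerase (Tpi1) differed by 0.45 ± 0.10 and muscle-type phosphofructokinase (Pfkm) by 0.45 ± 0.12 (SE, adjusted p = 0.655 for both). Immediate early genes, which are induced within minutes by stimulation, had lower signal: 19 of 25 were lower and the median was -0.088, with Klf4 at -0.41 ± 0.14 and Egr2 at -0.59 ± 0.22. The count of 8 lists was 8 in the test on ranks, 0 with an estimated correlation, 0 by fry for a shift in one direction and 0 by fry for changes in either. Without control replicate 3 it was 5, and without BPA replicate 1 or BPA replicate 3 it was 3 each.

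For the glycolysis list camera gave an adjusted p of 5.17e-05, and the call was lost at an adjusted p = 0.418 with an estimated correlation. Over 22 alternatives the adjusted p ranged from 7.04e-06 to 0.506, the highest from fry and not from camera. The immediate early genes had an adjusted p of 0.000236, and an adjusted p = 0.418 with an estimated correlation (1.59e-05 to 0.531 over 22 alternatives, the highest from fry). Both lists kept their call with each of the 6 arrays left out in turn. The mean of the glycolysis list was highest in BPA replicate 1 (0.25) and lowest in control replicate 3 (-0.23), as were those of the stellate cell and glia lists, and its member Pdgfra is also in the stellate cell list. The 3′ minus 5′ balance of control transcripts also differed between the groups. With it as a covariate camera lost the glycolysis call (adjusted p = 0.151), while the list's median stayed at 0.277. The test of immediate early genes turned without passing (adjusted p = 0.458), and their median was still negative (-0.0061). That balance separates the groups, so the fit with it removes much of the contrast. The call of immediate early genes was also lost with the mean of unannotated probe sets as a covariate (adjusted p = 0.171); both covariates were chosen after seeing the data. Heat shock proteins passed camera downwards with an adjusted p of 0.0106, or an adjusted p = 0.418 with an estimated correlation (0.00116 to 0.531 over 22 alternatives, the highest from fry). The list's estimated correlation was -0.013, below the preset 0.01, and camera's unadjusted p still rose from 0.00161 to 0.0270. A higher correlation between its genes therefore does not account for the loss of this call. Of 18 genes 14 were lower and the median was -0.086, with the chaperone genes Hsph1 at -0.25 ± 0.10 and Hsp90aa1 at -0.23 ± 0.10 (adjusted p = 0.748 and 0.787). Another probe set of Hsph1 differed the other way, by 0.12, and the other 2 of Hsp90aa1 by -0.96 and -0.46. The list's call was lost without control replicate 3 (adjusted p = 0.0565) and under cyclic loess (0.0567), and with each of the 2 covariates (0.0547 for unannotated probe sets and 0.0841 for the balance). None of the members of these 3 lists passed the test alone, either over all probe sets or adjusted over the list alone (smallest 0.0594).

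The lists of oxidative phosphorylation and ribosomal proteins passed camera with the preset correlation and had an adjusted p = 0.899 with an estimated correlation. Of the 65 measured oxidative phosphorylation genes 48 were higher, with a median of 0.11, and of 36 ribosomal protein genes 29 were higher, with a median of 0.091. Rps9 differed by 0.65 ± 0.16 and Rps3 by 0.26 ± 0.07 (SE), though the other probe sets of each lay between -0.098 and 0.00073. Camera gave an adjusted p of 0.00812 for oxidative phosphorylation and 0.0106 for ribosomal proteins. Over 22 alternatives each, the adjusted p ranged from 1.07e-06 to 0.899 and from 1.07e-06 to 0.991. Both calls were lost without control replicate 2, BPA replicate 1 or BPA replicate 3. Camera also lost both in 2 fits chosen after seeing the data. With both replicate 3 arrays left out the adjusted p was 0.161 and 0.186. With the 3′ minus 5′ balance of control transcripts as a covariate it was 0.717 and 0.991, with medians of 0.038 and -0.044.

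Of the lists of cell types other than the endocrine cells, those of glia and nerve, of stellate cells and fibroblasts and of immune cells passed camera upwards with the preset correlation, and each had an adjusted p = 0.899 with an estimated correlation. Those of acinar, duct, endothelial and fat cells did not pass. The means of the 3 lists that passed were highest in BPA replicate 1 (0.29 for glia and nerve, 0.42 for stellate cells and fibroblasts and 0.45 for immune cells, relative to the mean of the 6 arrays). Of 12 glia and nerve genes 10 were higher (median 0.24), with tyrosine hydroxylase (Th) at 10.41 ± 0.31 against 9.67 ± 0.21 (SD, n = 3 per group) and peripherin (Prph) at 8.40 ± 0.45 against 7.66 ± 0.57. Of 21 stellate cell and fibroblast genes 18 were higher (median 0.24), with Tagln at 0.40 ± 0.16 (SE). The fibronectin gene Fn1 differed by 1.72 ± 0.88, with 11.14 in BPA replicate 1, 7.32 and 8.46 in the other BPA arrays, and 7.19 to 7.33 in controls. Of 22 immune cell genes 18 were higher (median 0.18), with C1qa at 0.48 ± 0.15 and the lysozyme gene Lyz2 at 1.11 ± 0.52, again highest in BPA replicate 1 (10.77). With the 3′ minus 5′ balance as a covariate, a fit chosen after seeing the data, immune cells turned to a median of -0.36 (adjusted p = 0.0373), Lyz2 to -0.98 and Fn1 to -1.64. Neither gene passed in that fit. In it camera lost glia and nerve, though their median rose to 0.36 (adjusted p = 0.308), and stellate cells and fibroblasts (median -0.0074, 0.874). The balance separates the groups, so the turned values say little. In the main fit camera gave adjusted p of 0.0434, 0.0434 and 0.0444 to the 3 lists (0.00475 to 0.899, 0.00471 to 0.899 and 0.000484 to 0.899 over their alternatives). All 3 calls were lost without control replicate 3, BPA replicate 1 or BPA replicate 3, and that of immune cells also without control replicate 2. With each array left out the medians ran from 0.050 to 0.41, from 0.089 to 0.34 and from 0.049 to 0.28. All 3 were also lost with no filter on dim probe sets (adjusted p = 0.0761, 0.0761 and 0.151), that of stellate cells and fibroblasts with the filter at the 75th percentile (0.188) and that of immune cells under median centring (0.0533). With the mean of unannotated probe sets as a covariate, also chosen after seeing the data, all 3 were lost (adjusted p = 0.171, 0.316 and 0.244).

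**Figure D3:**
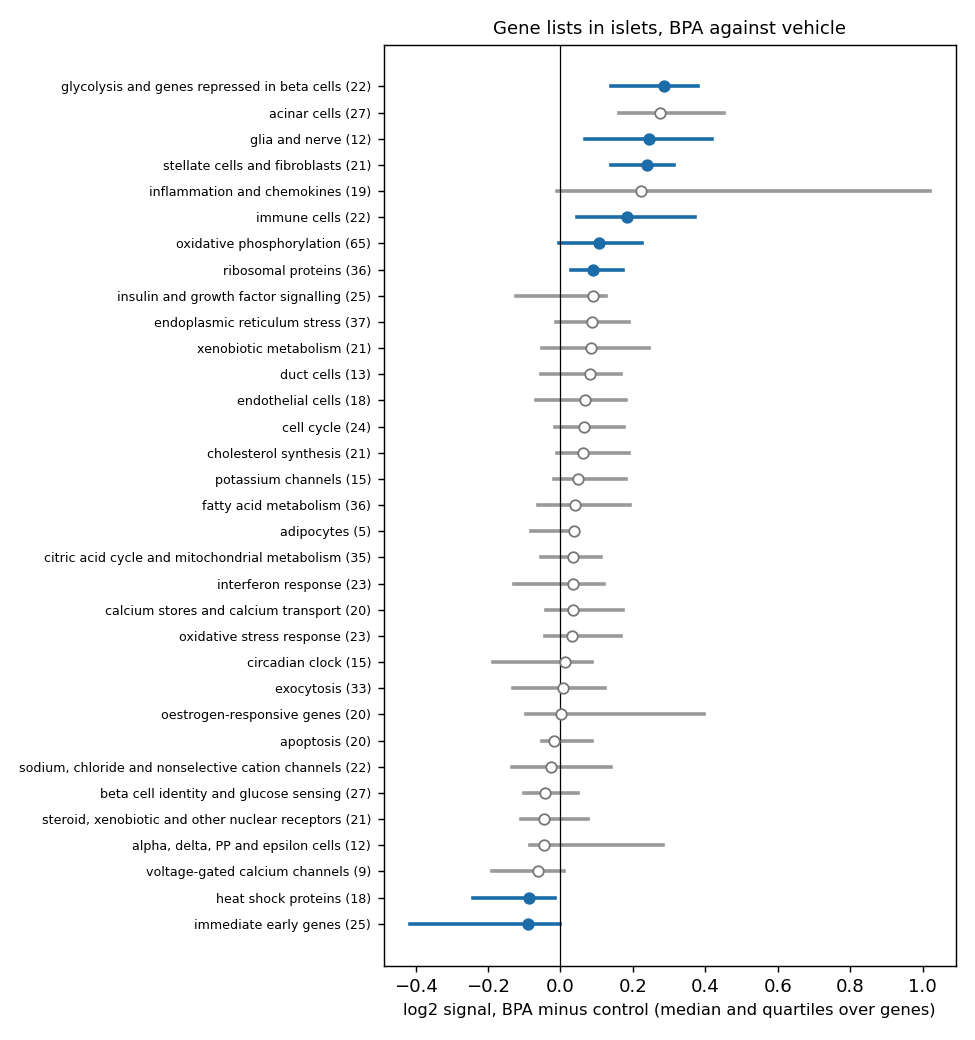
Median (point) and quartiles (line) over the measured genes of each of 33 lists of the log2 signal difference, BPA minus control (x axis); the number of genes is in brackets. Filled blue points are the 8 lists past camera with the preset correlation; the medians run from -0.088 for immediate early genes to 0.29 for glycolysis.

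Acinar cell genes, which mark exocrine tissue carried along with islets, ranged more between arrays than any other list. Relative to the mean of the 6 arrays the 27 genes averaged 0.33, 0.77 and -1.54 in control replicates 1 to 3 and 1.18, -0.09 and -0.64 in the BPA replicates. The group difference was 0.30 (exact permutation p = 0.8, two-sided, n = 3 per group), against a range of 2.31 within controls. Camera gave an adjusted p of 0.495. The list passed it with higher signal without control replicate 2 (median 0.75, adjusted p = 0.00116) and with lower signal without control replicate 3 (median -0.41, adjusted p = 0.00205), in a range of 0.00116 to 0.984 over 22 alternatives. The inflammation and chemokine list (median 0.22, adjusted p = 0.495) averaged 1.11 in BPA replicate 1 and -0.75 in control replicate 3, and passed without BPA replicate 2 (adjusted p = 0.00156, in a range of 0.00156 to 0.899 over 22 alternatives). Cell cycle genes averaged 0.31 in control replicate 3 and 0.30 in BPA replicate 3, and -0.20 to -0.10 in the other 4 arrays (adjusted p = 0.987). That list passed with the mean of unannotated probe sets as a covariate, a fit chosen after seeing the data (median 0.22, adjusted p = 0.0115, in a range of 0.0115 to 0.9985 over 22 alternatives).

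**Figure D4:**
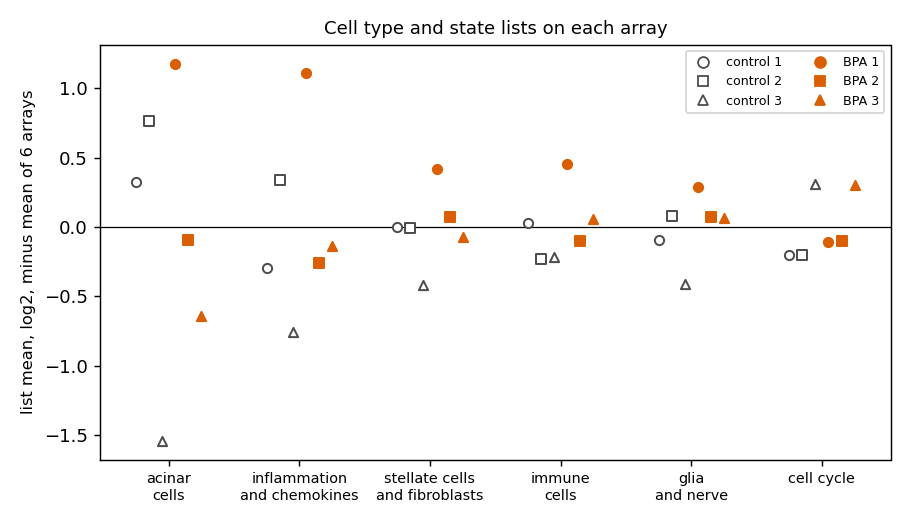
Mean log2 signal of 6 lists on each array, minus the mean of the 6 arrays (y axis); open symbols are controls, filled symbols BPA. Acinar genes run from -1.54 in control replicate 3 to 1.18 in BPA replicate 1, and cell cycle genes are highest in both replicate 3 arrays.

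Lists of endocrine function did not pass camera. Of 27 beta cell identity and glucose sensing genes 18 were lower (median -0.042, adjusted p = 0.138); the list passed without BPA replicate 2 (median -0.096, adjusted p = 0.000762, in a range of 0.000762 to 0.899 over 22 alternatives). Medians of the other endocrine lists were -0.047 for alpha, delta, PP and epsilon cells (adjusted p = 0.911) and 0.0065 for exocytosis (0.708). Ion transport lists had medians of -0.063 for voltage-gated calcium channels (0.495), 0.047 for potassium channels (0.708), -0.026 for sodium, chloride and nonselective cation channels (0.708) and 0.033 for calcium stores and transport (0.681). Steroid, xenobiotic and other nuclear receptors had a median of -0.046 (0.169) and oestrogen-responsive genes one of 0.0022 (0.987), with 10 higher and 10 lower. Xenobiotic metabolism had a median of 0.084 (0.708), and its member Gstm5 was the only gene of any list past the threshold adjusted over the list alone (0.0393), while adjusted over all probe sets it had 0.655.

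The remaining lists did not pass either. Adjusted p was 0.393 for cholesterol synthesis (median 0.063), 0.683 for endoplasmic reticulum stress (0.086), 0.495 for the circadian clock (0.013), 0.899 for the citric acid cycle (0.034), 0.911 for the interferon response (0.034) and for duct cells (0.082), and 0.987 for oxidative stress (0.031). It was 0.708 for endothelial cells (0.067), insulin and growth factor signalling (0.090), adipocytes (0.039), apoptosis (-0.018) and fatty acid metabolism (0.040). Endothelial cells passed in 2 fits chosen after seeing the data, with the mean of unannotated probe sets as a covariate (median 0.18, adjusted p = 0.0115) and with the 3′ minus 5′ balance of control transcripts as a covariate (median 0.40, adjusted p = 0.000105), in a range of 0.000105 to 0.984 over 22 alternatives. The median, the mean and the direction of the test differed in sign for 10 lists: circadian clock, sodium and related channels, insulin signalling, adipocytes, apoptosis, exocytosis, citric acid cycle, alpha and related cells, duct cells and oxidative stress. Red blood cell genes were too few to test.

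The array's control transcripts differed between the groups in their 3′ minus 5′ signal. The 3′ minus 5′ signal of Gapdh was 2.83 ± 0.22 after BPA and 3.56 ± 0.20 in controls, and that of beta-actin 2.81 ± 0.18 against 3.61 ± 0.23 (log2, SD, n = 3 per group). Among 7 such transcripts 5 were lower in all 3 BPA arrays, including 3 of the 4 bacterial transcripts added to the RNA (lys, phe and thr). For each of the 5 the exact permutation p was 0.1, two-sided, the smallest that 3 against 3 arrays can give. The 5 need not share 1 origin. For Gapdh the 5′ probe set was higher after BPA, by 0.92, while the 3′ probe sets of added lys and phe were lower, by -1.16 and -0.91. Probe sets with no annotated gene averaged -0.07, 0.14 and 0.23 in the control replicates and -0.22, -0.27 and 0.19 in the BPA replicates, relative to the mean of the 6 arrays (exact permutation p = 0.3, n = 3 per group).

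**Figure D5:**
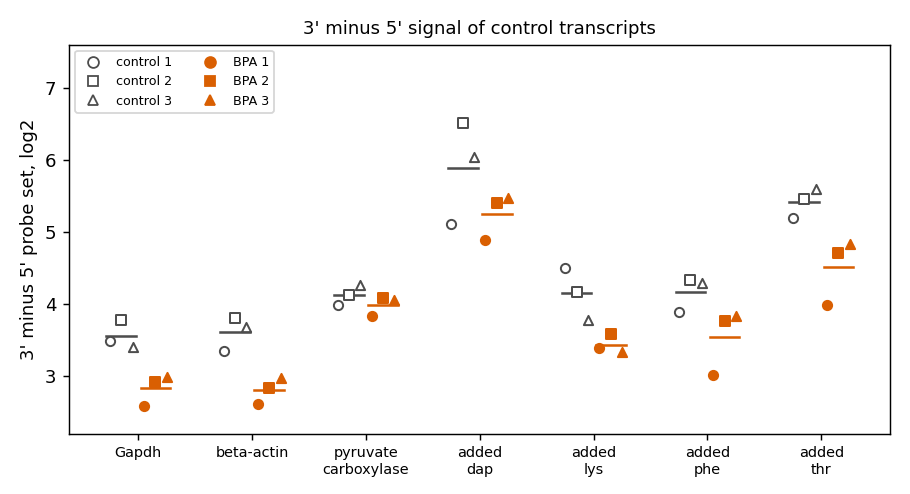
Log2 signal of the 3′ probe set minus that of the 5′ probe set (y axis) for 7 control transcripts on each array; open symbols are controls, filled symbols BPA, lines group means (n = 3), and "added" marks the 4 bacterial transcripts. BPA arrays lie below all controls for Gapdh, beta-actin, lys, phe and thr.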

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

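The control probe sets of the array, 64 in number, entered none of the comparisons of genes, and all tests in this part were chosen after the values were seen. Signal above every control array in all 3 BPA arrays was found for 4 of them. The 5′ probe set of Gapdh was higher by 0.92 (log2; 10.13 after BPA against 9.21 in controls), its middle probe set by 0.54 (11.84 against 11.30), the middle probe set of 18S ribosomal RNA by 0.40 (13.56 against 13.15) and the probe set for the middle of pyruvate carboxylase by 0.41 (6.80 against 6.39). In the other direction, 5 control probe sets were lower in all 3 BPA arrays, each the 3′ probe set of an added bacterial transcript. They belonged to lys, phe and dap only, since lys and phe each had more than a single such probe set. Chance alone gives 5% of probe sets in each direction, or 3.2 of 64. Probe sets of the same transcript, such as those of Gapdh, lys and phe, are not independent, so the counts can lie above that number without a separate cause for each. No explanation was tested for these probe sets one by one.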

How the results depend on the processing

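Alternatives with a covariate or with both replicate 3 arrays left out were chosen after seeing the data; the others were set before. The counts of probe sets with higher and lower signal were 0 in each alternative except the threshold of an unadjusted p under 0.05 with a 1.5-fold change, which gave 118 higher and 263 lower. The number of shifted gene lists, 8, was 5 with no filter on dim probe sets, 0 with the estimated correlation, 0 by fry, 2 with both replicate 3 arrays left out, 5 with the mean of unannotated probe sets as a covariate (3 of them among the 8) and 2 with the 3′ minus 5′ balance as a covariate (0 of them in the direction of the 8); leaving out each array gave 3 to 10. For each of these changes the cause was not tested. The 3′ minus 5′ balance of Gapdh and beta-actin separates the groups, so the fit with it removes much of the contrast. Its lost, turned or gained calls say little. The direction of immune cells turned with the 3′ minus 5′ covariate (median -0.36), as did the test of immediate early genes (median -0.0061), and that of acinar cells without control replicate 3 (median -0.41, in a range of -0.41 to 0.77 with each array left out). None of the 49 named genes passed in any alternative (smallest adjusted p 0.130), and 8 of them changed sign in at least 1. With a replicate block the counts were 0 higher, 0 lower and 8 lists. The labels do not say that the numbers pair the samples, so the main test had no replicate block. Deviations from the group means correlated at 0.476, 0.0781 and 0.706 for equal numbers, and BPA replicate 2 correlated best with control replicate 1 (0.397). Control replicate 3 correlated with BPA replicates 1 and 2 at -0.665 and -0.356. Deviations cancel out within a group of 3, so the low value of 1 pair cannot argue against a shared batch, which stays open. The median difference of all probe sets was -0.014 to 0.033 under the scalings. An offset before log2 was not run because the values already were log2. Dim genes such as Esr1 and Esr2 lie where signal over background sets the limit.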

Other observations

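Tests here were chosen after the results were seen, except the count of lists over other splits and the simulation of lists without an effect. The genes of this paragraph were chosen after their values were seen. Genes of the Reg family, secreted lectins of the exocrine pancreas, spread widely between arrays. Reg3a read 6.72, 11.02 and 5.94 in the control replicates and 13.40, 8.83 and 8.01 in the BPA replicates, and Reg2 read 11.09, 13.48 and 7.62 against 14.17, 10.44 and 10.52. The acute phase gene Saa3 read 11.06 in BPA replicate 1 and 6.25 to 8.09 in the other arrays. The proliferation genes Mki67 and Top2a read 9.90 and 8.14 in control replicate 3 and 9.78 and 8.31 in BPA replicate 3, while in the other arrays Mki67 lay between 7.25 and 7.81 and Top2a between 6.12 and 6.32. The noncoding RNAs Neat1 and Meg3 were also highest in both replicate 3 arrays: Neat1 at 12.21 and 11.90 against 9.77 to 10.30 elsewhere, and Meg3 at 13.74 and 13.44 against 11.67 to 12.87.

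The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In the real split 0 probe sets passed the threshold, a count that no split can fall below, and the highest other split gave 843. That split set control replicate 1 with BPA replicates 1 and 2 against the rest. Of its 827 probe sets higher in the rest, 547 had no annotated gene (66.1%, against 11.5% of those tested), which points to a structure of the samples that crosses the groups.

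Pattern 1 is that 8 gene lists passed camera while no gene did. Among the 10 splits 3 gave 8 or more lists, the real split included, and the highest other gave 10. In simulated data with no effect and the arrays' own correlation between genes, 14% of 100 sets gave 8 or more lists (median 5), so correlation between genes of a list may account for that number. All 8 calls stayed with the acinar mean as a covariate. That mean differed little between groups (0.30, against a range of 2.31 within controls). The fit could therefore hardly remove the calls, and it does not decide whether acinar RNA played a part. Bacterial transcripts were added to the RNA and do not come from the islets. For 3 of the 4 the 3′ minus 5′ signal was lower in all 3 BPA arrays (exact permutation p = 0.1 each). This points to a difference between the groups in how the arrays were made. Its share in the 8 lists cannot be told apart from that of BPA. The test of it used the balance of Gapdh and beta-actin only. The difference predicted from each gene's slope on that balance within groups correlated with the observed one across 11787 genes at 0.099. That was the 64.6th percentile of 1000 random directions, and genes are not independent replicates. Too few arrays keep open both a labelling effect and an effect of BPA on these lists.

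Pattern 2 is the range of acinar genes between arrays of both groups, where the mean of the 27 genes was 10.61 in control replicate 3 and 13.33 in BPA replicate 1. BPA as its whole cause was argued against by the range of 2.31 within controls, against a difference of 0.30 between groups. Exocrine tissue carried along in the isolation is a candidate explanation: 25 of the 27 genes were lowest on 1 and the same array, control replicate 3. For 26 of the 27 the 2 lowest arrays were control replicate 3 and BPA replicate 3, so low values were shared by both groups. Of these genes 1 (Nr5a2) is also in another list, and how many are transcribed by islet cells was not measured.

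Pattern 3 is that 2 of the 4 tested probe sets of Scn9a were lower in all 3 BPA arrays, while for the other 2, whose means were lower by less, the groups overlapped; none passed the test (adjusted p 0.655 or more). The mean of the 2 differed by -1.21 ± 0.30 (SE), and since they were picked for their difference this is a description and not a test. With the mean of unannotated probe sets as a covariate it was -0.9998 ± 0.318, which keeps 82.6% of its size. That covariate differed by only -0.1985 between groups (exact permutation p = 0.3), and the 2 probe sets were picked for their difference. The fit therefore does not decide on the share of unannotated transcripts as a cause. A BPA effect on some Scn9a transcripts, and a difference in labelling, may each apply and stay open as untested.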
